A study of Homo sapiens with 8 samples.

How the data were processed

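RNA bound to Musashi1 (Msi1), an RNA-binding protein of neural stem cells, was measured by RIP-chip in U251, an established human glioma cell line. In RIP-chip, a protein is immunoprecipitated with an antibody and the RNA that comes down with it is hybridised to a microarray. Here the RNA from the Msi1 immunoprecipitation and the RNA from an immunoprecipitation with prebleed serum were labelled with different dyes and hybridised to the same two-colour Agilent array. The 8 arrays came from 2 biological replicates, with 4 arrays each. In each replicate 2 arrays carried the Msi1 RNA in Cy3 and 2 carried it in Cy5. The 4 arrays of a replicate lay on a slide of their own, so slide and replicate cannot be told apart.

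The authors deposited scanner output with spot intensity values, which were not normalized, per the file headers. The submitters' processing notes name Agilent Feature Extraction 8.5, while the grid placement version in the file headers is 9.5.1.1. Probe positions in the files refer to the human build hg18 (NCBI36), per the file headers. The authors also deposited a table of log2 values for the same arrays. Its scale, centring and direction are stated in no source used here and were settled by comparison with the scanner values. Its rows follow the order of the spots in the scanner files. Each of its 8 columns correlated with the log2 ratio of Msi1 over prebleed computed here from the scanner files at r between 0.9955 and 1.0000, with slopes between 0.9933 and 1.0051, and the column medians lay between 0.0007 and 0.0097. No column of that table was left without a sample.

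From the scanner files, mean spot signals were background-corrected with normexp (offset 50) against the median local background and normalized within each array by loess in limma 3.58.1 under R 4.3.3. Control spots and spots with an outlier flag had weight 0 in loess. Flagged spots were then left out, between 91 and 227 of 43376 per array. Spots of a probe were averaged. Every log2 ratio was turned to Msi1 RIP over prebleed RIP. A probe was tested if it was well above background in the Msi1 channel, or in the prebleed channel, on at least 4 of the 8 arrays, which kept 30199 of 41000 probes. A gene was represented by its tested probe of highest mean intensity, which gave 22071 genes. Of these, 13020 were named through their accession in a RefSeq table of assembly GRCh38.p14, 964 through a symbol and 448 through a synonym. The other 7639 kept the name in the files. Members of the list of mitochondrially encoded transcripts were matched through synonyms without a hyphen.

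The arrays of a replicate were averaged within each dye orientation and then over the orientations, so that n = 2. The mean log2 ratio was tested against 0 with limma (lmFit on an intercept, then eBayes), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The prior carried 2.49 degrees of freedom and the total was 3.49. For 19 gene lists, cameraPR compared the moderated statistics of the list with those of all other genes at a preset correlation of 0.01, adjusted over the lists. A second value used the correlation estimated from the 8 arrays. It treats arrays of the same replicate as separate samples, so it is not a correlation between independent immunoprecipitations. The number of arrays and replicates limits the precision of every value.

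The genes named in the text followed a rule set before the data were examined. The 12 genes with the highest and the 12 with the lowest mean log2 ratio were taken among named genes past the threshold with the same sign on every array used, at least 6. MSI1 and MSI2, every tested member of the list of reported MSI1 targets, and up to 4 members with the smallest p of each other list were added. Some genes that the rule takes are not reported here. The lists, tests and most alternatives were also set before the data were examined. Alternatives covered background correction, normalization, filter, flagged spots, level of the test, dye orientation, choice of probe, empirical Bayes settings, the deposited table, single arrays and single replicates. Centring on added control transcripts, with and without loess, and a threshold of 0.1 were chosen after seeing the data. A planned test of Msi1 motifs in 3' UTRs was not analysed here, because it needs transcript sequences.

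The procedure was tested on simulated scanner signals for 22071 genes. Gene variances were drawn from the prior that limma fitted to these arrays. The spread between copies was that of the 2 replicate 1 arrays with Msi1 in Cy3. With 200 genes changed, it called 84.1% of genes changed 4-fold, 1.79% of those changed 2-fold and 0 of 81 changed 1.5-fold, and 5 of its 59 calls were false. With 6000 genes changed, it called 81.0% of genes changed 1.5-fold and 96.8% of those changed 2-fold, and 3.98% of its calls were false. A simulated list of 50 genes lowered 1.5-fold was called lower, and 0 of 100 unchanged lists had an unadjusted p under 0.05. The simulated genes varied independently of each other, whereas the correlation estimated within the real lists reached 0.26, for histones. The simulation therefore does not show how often correlated lists are falsely called. Dye effects of single probes were not simulated, and the variances followed the form that limma assumes. The shares of false calls therefore do not cover dye effects or noise particular to replicate 2.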

Results

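The comparison asked which mRNAs associate preferentially with Msi1 in U251 glioma cells. Between 66.2% and 78.9% of probes were well above background in the Msi1 channel and between 59.8% and 76.9% in the prebleed channel of the 8 arrays. Each value is a log2 ratio of Msi1 RIP over prebleed RIP, given as the mean ± SD of 2 biological replicates. Dyes were averaged first, so the SD does not show differences between the dye orientations.

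Transcripts from the mitochondrial genome and a varied set of nuclear mRNAs stood highest in the Msi1 RIP. COX1, a mitochondrially encoded subunit of cytochrome c oxidase, had a log2 ratio of 2.40 ± 0.19 (SD, n = 2), a 5.29-fold enrichment. It depended on the dye, with 1.40 to 2.08 on arrays with Msi1 in Cy3 and 2.93 to 3.02 with Msi1 in Cy5. CYTB, the mitochondrial cytochrome b, had 1.95 ± 0.08. Among nuclear genes, AASDHPPT, which modifies acyl carrier protein, had 2.21 ± 0.64. Membrane and secretory pathway genes in this group were HERPUD1, an endoplasmic reticulum stress gene (2.05 ± 0.01), ARL6IP1 (2.10 ± 0.49), and VAPA, a tether of the endoplasmic reticulum (1.95 ± 0.25). SDCBP, which encodes the scaffold protein syntenin, had 2.00 ± 0.09, TNFRSF19, a receptor of the tumour necrosis factor family, had 1.99 ± 0.11, and MED13L, a subunit of Mediator, had 2.00 ± 0.10. FANCF, of the Fanconi anaemia core complex, PCLAF, which binds PCNA, and ZFAND5 were also among the 12 most enriched, at 2.04 ± 0.42, 1.97 ± 0.43 and 1.93 ± 0.27. The HERPUD1 probe lies on chromosome 16 from 55535201 to 55535260 in hg18 and the SDCBP probe on chromosome 8 from 59657439 to 59657498. The files place the COX1 probe on chromosome 1 from 557430 to 557489. Probes of a gene could differ: the lowest tested probe had 0.23 for SDCBP, 0.12 for MED13L, 0.05 for PCLAF, 0.27 for VAPA, 0.64 for ZFAND5, 1.05 for AASDHPPT, 1.19 for TNFRSF19 and -0.01 for FANCF. Of 902 called genes with more than 1 tested probe, 74 had probes of opposite sign.

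The most depleted genes included 2 of mitochondrial proteins. ROMO1, which modulates reactive oxygen species, had -1.79 ± 0.03, and UQCR11, a subunit of respiratory complex III, had -1.53 ± 0.04. The lowest value was -2.15 ± 0.54 for ZSWIM9, a 4.43-fold depletion, followed by -2.12 ± 0.04 for PLEKHS1. The RNA-binding proteins TAF15 and PCBP2 had -1.89 ± 0.75 and -1.47 ± 0.26. CENPB, which binds centromeric DNA, had -1.51 ± 0.24, and CAMK2N1, an inhibitor of CaM kinase II, had -1.51 ± 0.01. IFI27L2, FN3K, LHPP and DOHH lay between -1.61 and -1.503. Another tested probe of UQCR11 had -0.24, of CAMK2N1 -0.68, of CENPB -0.76 and of LHPP -0.88. The ROMO1 probe lies on chromosome 20 from 33752255 to 33752314 and the PLEKHS1 probe on chromosome 10 from 115532061 to 115532120 in hg18.

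Over all 22071 genes tested, limma called 1430 enriched and 847 depleted after Benjamini-Hochberg adjustment. Without the second replicate 2 array with Msi1 in Cy3, 844 and 509 were called. Among the enriched genes 1421 had the same sign on every array used, and among the depleted genes 846. At least 2-fold higher in both replicates were 296 genes, 65 were at least 2-fold lower in both, and 0 moved 2-fold in opposite directions. Of the 14432 genes named through the RefSeq table, 1155 were called enriched and 612 depleted. Counts within gene lists are to be read against these shares. The smallest adjusted p was 0.0434, close to the threshold, and without the filter on dim probes limma called 0 genes in either direction (4462 higher and 4387 lower at an unadjusted p under 0.05). When the ratios were centred on the array maker's added control transcripts, with loess kept, the median of all genes moved to 0.79 and 13601 genes were called enriched and 12 depleted, in a fit where all genes shared 1 variance, so all directions given here are relative to the median gene.

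**Figure D1:**
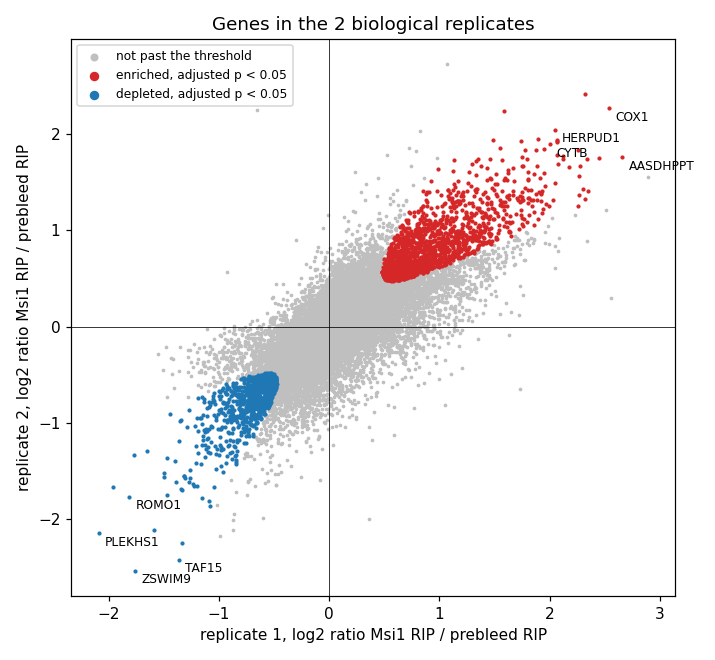
Log2 ratio of Msi1 RIP over prebleed RIP in replicate 1 (x axis) and replicate 2 (y axis), 1 point per gene, with the 1430 enriched genes in red, the 847 depleted genes in blue and all other tested genes in grey, relative to the median gene. Called genes lie in the quadrants where both replicates have the same sign.

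The replicates gave similar rankings of genes. Across genes, which are not independent replicates, Pearson's r of the 2 replicates was 0.773 and Spearman's rho 0.760, and 78.6% of genes had the same sign in both. Between dye orientations r was 0.908 in replicate 1 and 0.787 in replicate 2. Copies of an array within an orientation correlated at r between 0.853 and 0.983.

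Of mRNAs reported elsewhere as MSI1 targets, 4 of 19 tested rose in the Msi1 RIP and 0 fell. Whether any of them was first reported from these arrays is not known here, so the count is not independent evidence of direction. They were CCND1, which encodes cyclin D1 (1.52 ± 0.28, adjusted p = 0.0434 in limma), the receptor gene MET (1.20 ± 0.14), PDGFRA (0.89 ± 0.23) and TGFBR1 (0.82 ± 0.24). In replicate 2, TGFBR1 had 0.089 and 0.23 with Msi1 in Cy3 and 1.12 and 1.16 with Msi1 in Cy5. Adjusted over the list alone, 10 rose and 1 fell. NUMB, the Notch inhibitor first described as a Musashi target, had 0.69 ± 0.21 with an adjusted p of 0.0512 in limma. RB1, CDK6 and JAG1 had 1.502 ± 0.82, 1.00 ± 0.61 and 0.88 ± 0.42 and did not pass. EGFR had 0.40 ± 0.02 and ROBO3 -0.51 ± 0.12, also short of the threshold. CDKN1A, encoding p21, had 0.20 ± 0.04 and MYC 0.18 ± 0.07. The list median was 0.40 and the list shifted up (cameraPR adjusted p = 0.00159), but not with an estimated correlation (adjusted p = 0.217 with an estimated correlation). The Musashi mRNAs themselves did not pass the test, at -0.40 ± 0.07 for MSI1 and -0.16 ± 0.57 for MSI2. The lowest tested probe had -0.0048 for PDGFRA, 0.33 for MET, 0.17 for RB1, -0.13 for MYC and -0.12 for CDKN1A, and the highest for ROBO3 had -0.03.

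**Figure D2:**
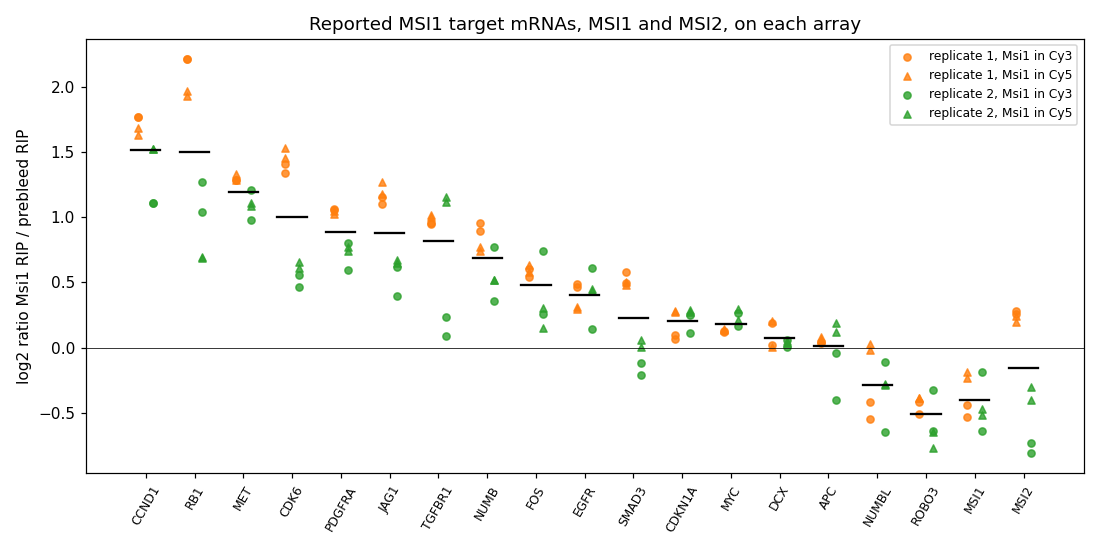
Log2 ratio of Msi1 RIP over prebleed RIP (y axis) on each array for members of the list of reported MSI1 target mRNAs, MSI1 and MSI2 (x axis). Colours mark the replicate, shapes the dye of the Msi1 RNA and bars the mean of the 2 replicates; CCND1 has the highest mean, 1.52.

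Nuclear mRNAs for the respiratory chain and the ribosome were lower, while mitochondrially encoded transcripts were higher. Of 57 nuclear-encoded oxidative phosphorylation genes, 24 fell and 3 rose, with a median of -0.46 (cameraPR adjusted p = 2.902e-12). COX7A2 had -1.44 ± 0.18, NDUFA1 -1.24 ± 0.16, UQCRQ -1.10 ± 0.05 and COX6B1 -1.05 ± 0.03. Of 77 cytosolic ribosomal protein genes, 17 fell and 2 rose, with a median of -0.33 (adjusted p = 3.781e-09). RPS29 had -1.43 ± 0.16, RPS21 -1.29 ± 0.18 and RPLP1 -0.93 ± 0.04, whereas RPL26 had 1.27 ± 0.17. Of 6 mitochondrially encoded transcripts, 4 rose and 0 fell, with a median of 1.47 (adjusted p = 1.476e-13). That list was set in advance as RNA not exposed to a cytoplasmic protein in cells. ND1 had 1.70 ± 0.22 and ND2 1.24 ± 0.21. The median of the mitochondrially encoded list depended on the dye, with 1.11 to 1.35 with Msi1 in Cy3 and 1.51 to 1.88 with Msi1 in Cy5. ND1 and ND2 were likewise higher with Msi1 in Cy5, whereas CYTB was similar in both orientations. These 3 lists and the cell cycle list kept their calls with an estimated correlation. For the cell cycle list the estimate was -0.0049, below the preset 0.01, so the second test was less strict there. Relative to the added controls, the ribosomal and respiratory medians were 0.47 and 0.34, below the median gene at 0.79.

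Genes of the cell cycle and of growth signalling were higher. Of 44 cell cycle genes, 7 rose and 1 fell, with a median of 0.23 (adjusted p = 0.00521 and 0.00159 with an estimated correlation). MKI67, a proliferation marker, had 0.79 ± 0.14, MAD2L1 of the spindle checkpoint 0.65 ± 0.02 and CDK1 0.60 ± 0.01. CDK1 depended on the dye, with 0.76 to 1.03 on arrays with Msi1 in Cy3 and 0.22 to 0.42 with Msi1 in Cy5. Of 42 genes of growth factor receptor and PI3K or MAPK signalling, 11 rose and 0 fell, with a median of 0.27 (adjusted p = 0.00144, and adjusted p = 0.0524 with an estimated correlation). The feedback inhibitors SPRY2 and SPRY4 had 0.98 ± 0.06 and 0.82 ± 0.02. Of 34 Wnt pathway genes, 5 rose and 1 fell (adjusted p = 0.0316, and adjusted p = 0.375 with an estimated correlation). The transcription factor TCF7L2 had 1.71 ± 0.35, the receptor FZD4 1.28 ± 0.24, and the secreted inhibitors SFRP1 and DKK1 had 1.29 ± 0.14 and 0.99 ± 0.05. Other tested probes went down to 0.62 for TCF7L2 and 0.02 for FZD4, and the Wnt list median was 0.30 in replicate 1 and 0.03 in replicate 2. With Agilent's processed signals the Wnt list lost its call (adjusted p = 0.0911). Of 29 Notch pathway genes 0 rose and 2 fell, HES4 at -0.72 ± 0.12 and LFNG at -0.54 ± 0.07, and the list did not shift (adjusted p = 0.983). Adjusted over the Notch list alone, 4 rose and 3 fell.

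Neural stem cell and astroglial genes, RNA-binding proteins and ubiquitin enzymes were also higher at the preset correlation. Of 24 neural stem cell and astroglial genes 3 rose and 0 fell (adjusted p = 0.00527, and adjusted p = 0.232 with an estimated correlation): SOX2 at 0.89 ± 0.02, NFIB at 0.86 ± 0.02 and VIM at 0.83 ± 0.17. VIM depended on the dye in both replicates. In replicate 1 it had 0.44 and 0.41 with Msi1 in Cy3 and 0.92 and 1.07 with Msi1 in Cy5. In replicate 2 it had 0.26 and 0.25 with Msi1 in Cy3 and 1.64 and 1.66 with Msi1 in Cy5. Another tested SOX2 probe had 0.37. Of 38 RNA-binding protein genes 6 rose and 0 fell (adjusted p = 0.00527, and adjusted p = 0.358 with an estimated correlation), with a median of 0.35 in replicate 1 and 0.08 in replicate 2, among them RBFOX2, a splicing regulator, at 1.05 ± 0.06 and PUM2 at 1.16 ± 0.29 (lowest tested probe 0.72). Of 39 ubiquitin ligases and deubiquitinases 4 rose and 0 fell (adjusted p = 0.00144, and adjusted p = 0.0551 with an estimated correlation), with TRIM2 at 1.15 ± 0.14. Of 40 adhesion receptor genes 4 rose and 0 fell (adjusted p = 0.0316, and adjusted p = 0.202 with an estimated correlation), among them CTNNA1 at 1.17 ± 0.27 (lowest tested probe 0.69) and ITGAV at 0.95 ± 0.33, and the call was lost with Agilent's processed signals (adjusted p = 0.096). Of 48 replication-dependent histone genes 0 rose and 5 fell, with a median of -0.35, or 0.45 relative to the added controls (adjusted p = 8.883e-06, and adjusted p = 0.217 with an estimated correlation). The histone median was -0.49 in replicate 1 and -0.18 in replicate 2. H2AC20 had -1.09 ± 0.01, and histone genes are near-identical, so single members are uncertain.

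The remaining lists did not pass the test. Of 34 apoptosis genes 5 rose and 1 fell (adjusted p = 0.14), with MCL1 at 1.66 ± 0.19, BCL2L11 at 1.06 ± 0.17 and BAX at -1.21 ± 0.33. The lowest tested probe had 0.48 for MCL1 and 0.38 for BCL2L11, and another BAX probe had -0.68. Of 42 translation factor genes 3 rose and 0 fell (adjusted p = 0.0636, and between 0.04223 and 0.0493, higher, under 4 alternatives), with EIF4EBP2 at 1.43 ± 0.17, whose lowest tested probe had 0.11. Of 37 splicing factor genes 5 rose and 2 fell (adjusted p = 0.839), with SRSF3 at 1.65 ± 0.12 and SNRPD2 at -0.95 ± 0.03. Of 31 proteasome genes 1 rose, PSMD6 at 1.04 ± 0.08, and 2 fell, PSMB3 and PSMB6 (adjusted p = 0.532). Of 38 extracellular matrix genes 2 rose, COL8A1 at 0.80 ± 0.10 and LOX at 0.61 ± 0.10 (adjusted p = 0.869), but adjusted over that list alone 0 rose and 0 fell. COL8A1 had 0.42 to 0.55 on arrays with Msi1 in Cy3 and 0.87 to 1.27 with Msi1 in Cy5. Of 17 markers of other cell types 1 rose, the synaptic gene SYT1 at 0.99 ± 0.24 (adjusted p = 0.778).

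**Figure D3:**
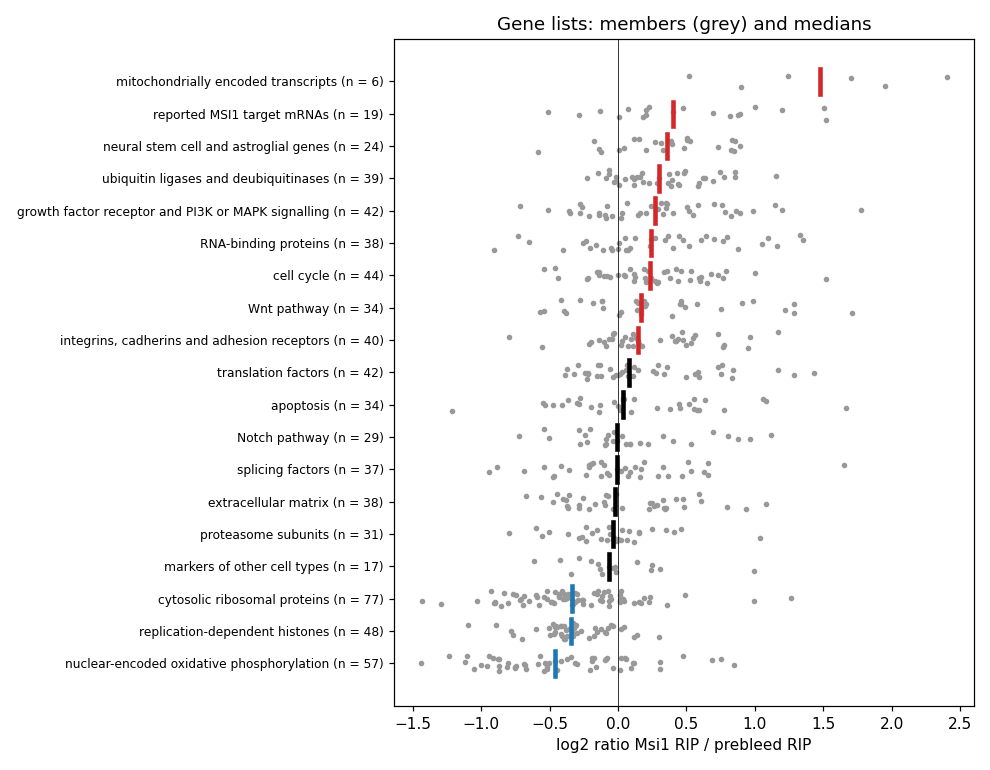
Log2 ratio of Msi1 RIP over prebleed RIP (x axis) of the tested members of each of the 19 lists (y axis, grey points), with the list median as a bar, red where cameraPR at the preset correlation called the list higher, blue where lower and black where it made no call, relative to the median gene. Medians run from -0.46 for oxidative phosphorylation to 1.47 for mitochondrially encoded transcripts; 4 of the 12 calls hold with an estimated correlation.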

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

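The tests of mitochondrial signal and of the added control transcripts were chosen after the result was seen, as were the requirements on spread added to the matched lists of ribosomal protein and respiratory chain genes.

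For 8 of the named genes and 1 list, a single array stood apart from the other 7, a rule that flags about 1 in 20 genes by chance. The first replicate 2 array with Msi1 in Cy3 gave -0.60 for PLEKHS1, -0.25 for FN3K, 0.35 for MKI67, 0.36 for SPRY4, 0.22 for CBLB and 0.057 for the median of growth factor receptor and PI3K or MAPK genes, each nearer 0 than the other arrays. The second replicate 2 array with Msi1 in Cy3 gave -0.40 for APC and 1.24 for ZFP36. The second replicate 2 array with Msi1 in Cy5 gave -1.03 for HES4. All these arrays belong to replicate 2.

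The array maker's control transcripts were added to the RNA and used in the report only as an alternative centring. Their ratio of Msi1 over prebleed was lower than that of the median gene. For this comparison the median gene was the median of all spots that are not controls, before loess and with dim probes kept. With dyes balanced, the log2 ratio of the median gene exceeded that of the controls by 1.06 in replicate 1 and 0.54 in replicate 2. Arrays of the same orientation differed by at most 0.51 and 0.19. The smaller gap, -0.54 for controls minus median gene, exceeds that spread, which is what unequal RNA in the 2 immunoprecipitations would give and may be its cause. The controls were brighter than that median spot on every array, so a difference tied to signal intensity cannot be told apart from unequal RNA. Single controls were not equal in the 2 dyes. Their red over green (log2) ran from -0.43 to 5.92 on the first replicate 1 array with Msi1 in Cy3. On the first replicate 1 array with Msi1 in Cy5 it ran from -2.04 to 4.10. Their order was alike on every array (Spearman's rho with the former array 0.939 or more), so the gap rests on balancing the dyes. The amounts of control added to each sample are not given in the sources used here, and no biological explanation was tested.

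Ribosomal protein and respiratory chain mRNAs were lower than the median gene. Dye bias is argued against, since both medians were below 0 on 8 of 8 arrays. Among 10000 random lists matched on mean intensity both medians lay at percentile 0. Loess had already brought genes of like intensity close to 0 (random medians 0.0094 for ribosomal proteins and 0.0060 for the respiratory chain). That match therefore shows only that both lists lie below genes of like intensity, and does not decide on bias tied to signal intensity. With median centring and no loess the medians were -0.54 and -0.47. In lists matched on genomic gene length and intensity the respiratory chain median lay at percentile 0. It was 0.195 below the bound set before the test (the 2.5th percentile), against an SD of 0.077 between its replicate medians. This argues against short genomic length as the whole explanation there, but after loess it does not decide on signal intensity. Random genes were drawn singly, whereas the correlation estimated within the respiratory chain list was 0.053, so the bound may be too narrow. The ribosomal protein median lay at percentile 2.15, 0.0021 below its bound, or at percentile 1.76, 0.0047 below it, with 10 length classes in place of 5. Both distances are less than the SD of its replicate medians (0.0098), so short genomic length and signal intensity stay open for ribosomal proteins. The comparison with the SD was added after the result was seen and turns the planned verdict for ribosomal proteins only, while a bootstrap requirement tried earlier left both open (upper bounds of the medians -0.26 for ribosomal proteins and -0.20 for the respiratory chain); genomic length is not mRNA length, and with 1 group of arrays no biological explanation was tested.

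Mitochondrially encoded transcripts were higher. Of 17 tested probes that the files place on the mitochondrial genome, 16 were above 0 in both replicates, with a median of 0.96. That median lay at percentile 100 of random probe lists matched on mean intensity. Loess had already brought probes of like intensity close to 0, so this match does not decide on bias tied to signal intensity. The median of the mitochondrially encoded list was 1.47 with loess and 1.46 with median centring and no loess. Whether carry-over of mitochondrial RNA as a whole or association with Msi1 raised these transcripts is not decided. Of the probes, 94.1% were above 0 in both replicates, but these include the probes that prompted the test, and both explanations predict that share. The list was set in advance as RNA not exposed to a cytoplasmic protein in cells. Its rise limits how far enrichment in the Msi1 RIP can be read as binding in cells.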

How the results depend on the processing

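Counts of genes past the threshold moved with the processing, while directions mostly held: all 2277 called genes kept their sign with processed signals, median centring, no background correction, flagged spots kept, either dye orientation alone, the mean of a gene's probes, the deposited table and each array left out, 1692 did when centred on added controls with loess kept, and 1654 when also without loess. Of the called genes, 1421 of 1430 enriched and 846 of 847 depleted had the same sign on every array used. For these, the sign in a dye orientation alone or with an array left out was fixed in advance and is no evidence of stability. Counts, enriched then depleted, were 1430 and 847 in the report. They were 3094 and 2163 with Agilent's processed signals, 3617 and 1666 with median centring and no loess (where the prior degrees of freedom were infinite, so that all genes shared 1 variance), 0 and 0 with no filter on dim probes, 2063 and 1372 with both channels above background on all arrays, 5085 and 4800 with all arrays and the biological replicate as a random block, 4879 and 4506 with a dye term added, 2223 and 1622 with only Msi1 in Cy3, 648 and 205 with only Msi1 in Cy5, 1841 and 1377 with the mean of a gene's probes, and 2361 and 1339 over all probes. The fits on all arrays used arrays of the same replicate as observations, with a correlation within replicates of 0.27, or 0.41 with the dye term. Their counts therefore do not rest on n = 2 and are not comparable with the others. Leaving out 1 array gave 844 to 1915 and 509 to 1284. The lowest counts came without the second Cy3 array of replicate 2 and the highest without the first Cy3 array of replicate 1. At a threshold of 0.1, chosen after seeing the data, they were 3499 and 2955. Centring on added controls, also chosen after, gave 13601 and 12 (99.9% of calls enriched against 62.8%), and without loess as well 11477 and 15 (99.9% against 68.5% with median centring and no loess); in both the prior degrees of freedom were infinite. With loess kept it put HES4 at 0.078, LFNG at 0.26, H2AC12 at 0.021, H4C11 at 0.035, PSMB3 at 0.0052, PSMB6 at 0.245 and SNRPA at 0.12, and without loess HES4 at 0.15, LFNG at 0.33, H2AC12 at 0.12, H4C11 at 0.070, PSMB3 at 0.055, PSMB6 at 0.16 and SNRPA at 0.070, none of them past the threshold. The correlation of the replicates was 0.773 in the report, 0.730 with processed signals, 0.714 with median centring and 0.711 with only Msi1 in Cy5. With an estimated correlation, 2 lists in place of 9 shifted up. With processed signals 7 did, since the Wnt and adhesion lists lost their calls (adjusted p = 0.0911 and 0.096), and with only Msi1 in Cy3 the adhesion list lost its call (0.0676). The cause was not tested except where fewer genes or arrays entered by construction. Aquantile normalization changed no value by construction. Over named genes and alternatives with a test, 2361 values stayed on their side of the threshold, 145 passed it anew, 177 lost it (84 of these with no filter) and 14 reversed, all when centred on added controls. Over lists, 441 stayed, 11 lost it and 4 passed anew, all of them translation factors higher: with a dye term (adjusted p = 0.04224), with only Msi1 in Cy3 (0.0493), and without the first Cy5 array of replicate 1 (0.04223) or the second Cy3 array of replicate 2 (0.04496). A single replicate gives no test; MSI2 had 0.25 in replicate 1 alone and -0.56 in replicate 2 alone. The alternatives of the motif test were not run.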

Other observations

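The tests of the small GTPase family were chosen after the result was seen; those of the other families and of gene length were set before. Genes of mitochondrial ribosomal proteins, taken by symbol, were lower: 14 of 77 fell and 4 rose, with a median of -0.23, and the family shifted down (cameraPR adjusted p = 0.0007143 over 4 families). ZNF zinc finger genes were higher, with 32 of 416 enriched, 11 depleted and a median of 0.15 (mRNAs of zinc finger proteins shifted, adjusted p = 0.0007143). Their enriched share was close to that of all 14432 named genes, of which 1155 were enriched and 612 depleted. The count of enriched ZNF genes alone therefore does not set the family apart. Small GTPase genes, without those named among the most enriched, had a median of 0.14 (0.20 in replicate 1 and 0.05 in replicate 2), with 13 of 113 enriched and 4 depleted (adjusted p = 0.01007). With an estimated correlation none of these 3 calls held (adjusted p = 0.234 for each). Of 440 solute carrier and TMEM genes 52 were enriched and 27 depleted, with a median of -0.01, and the family did not pass the test (adjusted p = 0.5745). With members called on both sides, whether membrane protein mRNAs are enriched as a class stays open, although the bound set before the test would have ruled it out.

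Longer genes were higher in the Msi1 RIP. Spearman's rho of the log2 ratio and genomic gene length was 0.34 in replicate 1 and 0.29 in replicate 2 (0.2889), across 14396 genes that are not independent replicates. A length-related difference between the immunoprecipitations may therefore contribute to lists of short or long genes; mRNA and 3' UTR lengths were not analysed here.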
